A study of Homo sapiens with 6 samples.

How the data were processed

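The samples were 6 ChIP-seq libraries of a HepG2 clone carrying V5-tagged TAF2, 3 from the V5 immunoprecipitation and 3 controls, grouped by the treatment given in the labels. The labels call the controls input in the treatment, input DNA in the sample titles and IgG in the library names. Only the peak lists of the 3 V5 libraries were used, and the controls entered no test, so no background measured in control samples stands beside the values. Whether the libraries came from separate cultures is not stated. Per the labels the genome build was GRCh38. The aligner, the peak caller, its threshold and the control behind each list are not given in the sources used here.

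Each deposited list held a line per peak in the narrowPeak layout. The authors' fold enrichment of a peak is a linear ratio over the background their caller used. The deposited -log10 p and -log10 q of each peak were taken as the authors' caller gave them. The deposited score of a peak equalled 10 times its -log10 q cut to a whole number and was not used. The deposited summit is an offset in bp from the start of the peak, counted from 0. Fold and -log10 q were used only within a list, to rank, describe or filter peaks, and ranks are given as percentiles of the list. The deposited values carry no read counts, so depth is unknown. The binomial intervals are exact (Clopper-Pearson) at 95% and cover counting error only.

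The gene table of GRCh38 used here gives the span and type of each gene, without strand, transcripts or sequence. The planned promoter windows around transcription starts were therefore replaced by windows of 1000 bp either side of either annotated end of a gene, and the planned exon, intron and untranslated classes by 5 classes. A gene's start cannot be told from its 3′ end in these windows. The planned comparison of core promoter sequence needs the genome sequence and was not made. Of 20050 protein-coding genes, 19987 on chromosomes that hold peaks were tested.

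Peaks of the 3 lists that overlapped by at least 1 bp were merged into regions, and a region with peaks of at least 2 libraries was called reproducible. A gene was called bound with a peak at an end in at least 2 libraries. These peaks need not overlap or lie at the same end. Random placement moved each peak within its chromosome 1000 times, over the annotated span without gene-free stretches above 1000000 bp. Contigs without annotated genes were left out of the gene-end share, class and distance tests, which left 1574, 2531 and 1860 peaks in replicates 1, 2 and 3. The overlap of libraries, the shared regions and the comparisons of strength kept the contig peaks, which could not be placed at random, so they count among the observed overlaps and not among those by placement. Differences in median percentile were tested with 100000 resamples, two-sided. Gene lists were tested with the two-sided Fisher's exact test, and chromosomes with two-sided exact binomial tests against their share of protein-coding genes. Adjusted p-values are Benjamini-Hochberg values over the libraries, lists, classes or chromosomes of the comparison, with a threshold of 0.05. A region wider than 2000 bp was called wide, and a 100 kb window with 5 or more peaks of a library a dense cluster.

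The comparisons, groups, gene lists, rule for naming genes and first set of alternatives were chosen before the data were examined. The rule named TAF2 and the other TFIID subunits with a peak, the strongest 20 end regions by mean percentile, up to 4 bound members of each list, the 10 strongest regions in 3 libraries away from gene ends, and the strongest 3 end genes of each library alone. Some items that the rule names are not reported here. Further list members, the genes with a divergent partner and the genes of wide regions and dense clusters were named after their values were seen. The comparisons of gene types, divergent partners and wide regions were also chosen after the data were seen, and the closing section says when each of its own tests was chosen. Alternatives covered stricter peaks (-log10 q of at least 3 or 5, fold of at least 5, the strongest 1000), other windows (250 and 2000 bp, or the summit inside), other overlap rules, the number of libraries, the chromosomes used, dense clusters and each replicate left out.

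The code was tested on simulated data with peaks of 200 bp. Of 100 sets of 1500 randomly placed peaks, 7% passed the threshold of the gene-end test. With 2, 5 and 15% of peaks implanted at gene ends, all 20 sets passed and the mean excess was 2.00, 4.89 and 14.5 percentage points. All 600 regions implanted in 3 libraries were found. Of 50 sets of randomly bound genes, 2% gave any list past the threshold, and a proteasome list bound at 15% was found in 84% of 50 sets. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.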

Results

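The series measured where a V5-tagged form of TAF2 was recovered on chromatin of HepG2 cells, by chromatin immunoprecipitation and sequencing (ChIP-seq). HepG2 is an established human liver cancer line with many features of hepatocytes. TAF2 is a subunit of TFIID, the general transcription factor complex that assembles at core promoters ahead of RNA polymerase II, and V5 is a short peptide tag recognised by an antibody. The labels gave 3 libraries from the V5 immunoprecipitation and 3 control libraries. The control samples were called input in their treatment label, input DNA in their titles and IgG in their library names. The labels did not resolve this conflict, and no peak list of the controls was analysed here. Each V5 library came with its own list of peaks on GRCh38. The lists held 1599, 2557 and 1887 peaks in replicates 1, 2 and 3, a mean of 2014 ± 492 (SD, n = 3), and covered 523, 777 and 592 kb. Median peak width was 220, 224 and 224 bp. The fold of a peak over background is the authors' value for that peak and was used only to describe and rank peaks within their own list. Its median was 5.01, 5.25 and 5.03, and its highest value was 25.2, 27.3 and 30.8. The lists give no read totals, so the depth of the libraries is unknown. The labels do not say whether the 3 libraries came from separate cultures, and tests over peaks or genes describe these lists, since neighbouring peaks and genes are not independent replicates.

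The first comparison asked how far the 3 V5 lists named the same places. Among the strongest of the shared regions were those at the lower annotated end of FAM117B, at an end of and inside C14orf93, at neighbouring ends of POLR1B and TTL, over TRA2B and TRIM71, and at the sterol synthesis genes HMGCS1, SREBF2 and FDFT1. Of the 1599 peaks of replicate 1, 971 (60.7%) overlapped a peak of replicate 2 and 827 (51.7%) a peak of replicate 3. Of the 2557 peaks of replicate 2, 1049 (41.0%) overlapped a peak of replicate 3. Random placement on the same chromosomes gave means of 12.4, 10.7 and 10.3 overlapped peaks for these pairs. Each observed count was above all 1000 placements (permutation test, one-sided, adjusted p = 0.001, the smallest the placements can give). Merging the lists gave 3783 regions, of which 647 held peaks of 3 libraries, 743 of 2 libraries and 2393 of 1 library. The 1390 regions with peaks of at least 2 libraries are called reproducible here. Placement gave 8.48 ± 2.19 such regions (SD over placements). Peaks in reproducible regions ranked higher by fold than peaks of 1 library alone, by 17.9, 24.4 and 21.2 percentile points of the median in replicates 1, 2 and 3 (two-sided permutation test, adjusted p = 1e-05 in each, the smallest the resamples can give). Without replicate 2 the shared regions numbered 792, and without replicate 3 they numbered 917.

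TFIID binds core promoters, so the next comparison set promoters against the rest of the genome. The gene table used here gives no strand and no transcripts. Peaks were therefore scored within 1000 bp of either annotated end of a protein-coding gene, and a peak at a start cannot be told from a peak at a 3′ end. A transcription start farther inside the span of a gene lies outside these windows, so a peak there counts as inside the gene. The gene-end share is therefore not a promoter share. Of the reproducible regions on sequences with annotated genes, 259 of 1366 lay at such an end, 19.0% (exact binomial 95% interval 16.9 to 21.1%), against 4.30% under random placement, a ratio of 4.41 (permutation test, one-sided, adjusted p = 0.001, the smallest possible). The share was 17.2% in replicate 1 (15.3 to 19.1%), 16.8% in replicate 2 (15.4 to 18.3%) and 24.8% in replicate 3 (22.8 to 26.8%). Replicate 3 lay above replicates 1 and 2 (two-sided Fisher's exact test, adjusted p = 7.6e-08 and 2.71e-10), and replicates 1 and 2 did not differ detectably (adjusted p = 0.765). Among peaks of a single library, 33.7% of those in replicate 3 were at a gene end, against 18.2% in replicate 1 and 17.01% in replicate 2. Among peaks in regions of all 3 libraries the shares were 16.6, 15.4 and 16.5% in replicates 1, 2 and 3.

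**Figure D1:**
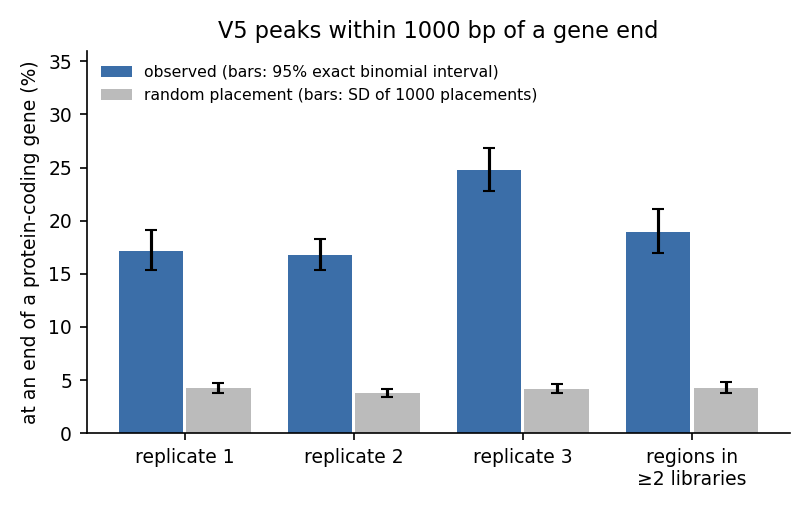
Share of V5 peaks or regions within 1000 bp of an annotated end of a protein-coding gene, in percent, for each replicate and for regions with peaks of at least 2 libraries. Blue bars show the observed share with its exact binomial 95% interval and grey bars the mean of 1000 random placements with their SD; the observed shares of 16.8 to 24.8% stand above the 3.78 to 4.30% of random placement.

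Placed by their summits, 15.4% of reproducible regions fell at a protein-coding gene end against 3.63% by placement, and 9.004% at an end of another gene against 4.28%. Intergenic summits made up 22.5% against 37.1% by placement, and summits inside other genes 8.78% against 12.2% (two-sided permutation test over placements, adjusted p = 0.0025 in each of these 4 classes). Summits inside protein-coding genes, away from their ends, made up 44.3% against 42.8%, which did not differ detectably (permutation test, adjusted p = 0.296), although this class was in excess in replicate 1 (48.5 against 42.5%) and replicate 2 (47.8 against 42.7%, adjusted p = 0.002 in each, the smallest possible) and not detectably in replicate 3 (43.8 against 42.8%, adjusted p = 0.398). The depletion inside other genes was lost without replicate 3 (9.82%, permutation test, adjusted p = 0.0549). The median summit lay 11359 bp from the nearest protein-coding gene end, against 46499 bp by placement (permutation p = 0.002, the smallest a two-sided test over the placements can give), and 8.78% of summits lay within 250 bp, against 1.17% by placement. Peaks at gene ends ranked lower by fold than other peaks of their list, by a median difference of -8.47, -8.19 and -12.7 percentile points in replicates 1, 2 and 3 (two-sided permutation test, adjusted p = 0.00918, 0.0028 and 3e-05). With peaks ranked by −log10 q instead, the difference passed the threshold in replicate 3 and not in replicate 1 (-2.08, adjusted p = 0.566) or replicate 2 (-4.26, adjusted p = 0.165) in the same permutation test.

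The tagged gene itself, TAF2 (chromosome 8, 119730774 to 119832841), had no peak over its span or within 1000 bp in any library, and the nearest peak lay 613 kb away, in replicate 2. Among the other subunits of TFIID, TAF12 alone had a peak at an end, in replicate 1 only (chromosome 1, 28648407 to 28648591, fold 5.13), and that peak also lay within 1000 bp of RNU11, a gene for a small RNA of the minor spliceosome. At an end of 274 of 19987 protein-coding genes (1.37%) a peak was present in at least 2 libraries, and these genes are called bound here. The peaks of a bound gene need not overlap between libraries or lie at the same end. The count was 125 with 3 libraries, 802 with any library, 163 without replicate 2 and 157 without replicate 3. Of the bound genes, 13 are those of the mitochondrial genome.

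By mean rank percentile over the 3 libraries, the highest-ranked end peak was at FAM117B (chromosome 2, 202634389 to 202634969), with folds of 25.2, 26.7 and 30.8 in replicates 1, 2 and 3. It ran up to the lower annotated end of the gene. C14orf93 followed (chromosome 14, 23008708 to 23010735), with folds of 24.4, 27.0 and 24.4, and ranked above FAM117B in replicate 2. A region just inside the lower end of POLR1B, which encodes a subunit of RNA polymerase I, and within 1000 bp of the neighbouring end of TTL, a tubulin tyrosine ligase gene, had folds between 18.1 and 19.7 (chromosome 2, 112542200 to 112542713). TRA2B, a splicing regulator, had a region 9849 bp long over its upper end (chromosome 3, 185928343 to 185938191), with folds between 14.3 and 15.8. Others among the strongest 20 regions lay, in rank order, at HMGCS1, SREBF2 with CCDC134, DHRS13, SNX5 with MGME1, NEMP1 with NAB2, SQLE, BCAN, ERRFI1, EML4, UGDH, SRSF3, MDM2, ZNFX1, TWF2 and MT2A. Their mean rank percentile ran from 99.5 ± 0.38 at HMGCS1 to 93.3 ± 1.51 at MT2A (SD, n = 3). Some wide regions reached an end only by their edge, with summits well away from it. The distance was 2367 to 3751 bp at TRA2B, 1880 to 4688 bp at ERRFI1, 2700 to 3704 bp at EML4 and 1485 to 3973 bp at UGDH. The region listed at ZNFX1 lay outside that gene, over the noncoding RNA gene ZFAS1, with summits 3456 to 4109 bp from the end. MDM2 encodes the ubiquitin ligase of p53, MT2A a metallothionein, ERRFI1 an inhibitor of EGF receptor signalling and UGDH a UDP-glucose dehydrogenase.

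The strongest end genes of a single library with no end peak in the others were LYZL2, IARS2 and KPNA2 in replicate 1 (folds 8.10, 6.96 and 6.72). In replicate 2 they were USHBP1, CYP4F3 and RPL34 (folds 8.26, 7.90 and 7.87), and in replicate 3 EPB41L4B, KLF3 and SNX24 (folds 9.51, 8.50 and 8.18).

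Fixed gene lists were then compared with all other protein-coding genes. Genes of sterol and lipid synthesis were bound most often, 11 of 33 (33.3%) against 1.32% of other genes (two-sided Fisher's exact test, odds ratio 37.4, 95% interval 16.2 to 81.4, adjusted p = 7.01e-12). With an end peak in any library they no longer ranked first, at 15 of 33 against 19 of 40 abundant housekeeping genes. The bound members included HMGCS1, MVK, MVD, FDPS, SQLE, LSS and MSMO1 of the cholesterol pathway, the sterol transfer gene STARD4, and SREBF2, which encodes the transcription factor that controls this pathway. HMGCS1 (chromosome 5, 43313597 to 43313922) had folds of 11.0, 18.4 and 13.9 and SQLE (chromosome 8, 124998115 to 124998534) folds of 8.70, 11.8 and 10.4. SREBF2 (chromosome 22, 41832691 to 41833194) had folds of 14.8, 13.9 and 12.2. The peaks at MSMO1 and FDPS were also present in 3 libraries, and those at LSS, MVD, MVK and STARD4 in 2. The fatty acid synthesis genes FASN and SCD had an end peak in 1 library each, and ACLY, ACACA and ELOVL6 in none. Over the gene or within 1000 bp of it, ACACA had a peak in 3 libraries and ACLY and ELOVL6 in 1 each.

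Abundant housekeeping genes followed, with 11 of 40 bound (27.5%, Fisher's exact test, odds ratio 28.4, interval 12.6 to 59.2, adjusted p = 3.85e-11). They included HSPD1 and HSPE1, which encode mitochondrial chaperones and share a region (mean rank percentile 80.8 ± 12.4, n = 3), the ferritin gene FTL (75.5 ± 26.1) and the nucleolin gene NCL (52.9 ± 33.1). Hepatocyte genes were bound in 14 of 86 cases (16.3%, Fisher's exact test, odds ratio 14.7, interval 7.55 to 26.7, adjusted p = 6.7e-11). These were the plasma protein genes AFP, AHSG, AMBP, C3, F2, FGG and VTN, the apolipoprotein genes APOA1, APOA2 and APOB, the fatty acid binding protein gene FABP1, and the regulators FOXA1, FOXA3 and NR0B2. In the 5 bound in 3 libraries, the mean rank percentile was 69.5 ± 14.3 at FOXA3, 65.2 ± 38.2 at APOA2, 61.8 ± 27.0 at NR0B2, 33.9 ± 30.4 at AMBP and 25.3 ± 16.2 at APOB (SD, n = 3), so that peaks at some of these genes ranked far apart between libraries.

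Liver cancer genes (4 of 45, adjusted p = 0.0149: AFP, CCND1, LGR5 and NFE2L2) and spliceosome genes (4 of 60, adjusted p = 0.0277: SRSF3, HNRNPC, HNRNPA2B1 and DDX5) also passed the threshold, with odds ratios of 7.11 and 5.20 in the exact test. The strongest end peaks of DDX5 lay at opposite ends of the gene in replicates 2 and 3. Those of AFP in replicates 1 and 2 did not overlap. Olfactory receptor genes, which are silent in most tissues, were bound in 0 of 390 cases, against 1.40% of other genes (Fisher's exact test, adjusted p = 0.0263). Gene length was not accounted for here, since the alternative with gene length was not run for a list without bound genes. These last 3 calls were lost without replicate 2 (exact test, adjusted p = 0.156, 0.0584 and 0.208), and that on olfactory receptors also without replicate 1 (adjusted p = 0.106) or replicate 3 (adjusted p = 0.179). They were also lost among peaks with −log10 q of at least 3 (exact test, adjusted p = 0.183, 0.0938 and 0.116) and without dense clusters (adjusted p = 0.19, 0.0806 and 0.0806). The spliceosome odds ratio fell to 2.65 with the summit inside the window (exact test, adjusted p = 0.352), where HNRNPC and DDX5 kept an end peak in 1 library each, and to 1.92 with a 250 bp window (adjusted p = 0.579).

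Of the other lists, the cytosolic ribosomal protein genes came nearest, with 4 of 79 bound (RPL13A, RPL4, RPS29 and RPL27, odds ratio 3.88, Fisher's exact test, adjusted p = 0.0599). That list passed the threshold with a 2000 bp window (4.26, exact test, adjusted p = 0.00919), with a peak in any library (3.91, adjusted p = 0.000911) and without dense clusters (4.97, adjusted p = 0.0471). It did not pass in 13 of 16 settings, and its odds ratio was 1.56 without replicate 2 (exact test, adjusted p = 0.681). None of the 30 genes of TFIID and the general transcription factors was bound (odds ratio 0, interval 0 to 9.46, exact test, adjusted p = 1), and an interval of that width excludes little. Bound genes numbered 2 of 32 among immediate early genes (IER3 and KLF6, exact test, adjusted p = 0.16) and 3 of 85 among translation factors and tRNA synthetases (EIF4A2, EEF1A1 and TARS1, adjusted p = 0.223). They numbered 2 of 63 in the cell cycle list (CDKN1B and CCND1, exact test, adjusted p = 0.385) and 1 of 27 in the unfolded protein response (XBP1, adjusted p = 0.509). A single gene was bound in the lists of proteasome subunits (PSME2 of 48, exact test, adjusted p = 0.727), replication-dependent histones (H4C12 of 68, adjusted p = 0.731) and genes of neurons, muscle and blood (LYZ of 67, adjusted p = 0.731). The same held for mitochondrial ribosomal proteins (MRPS18B of 77) and nuclear genes of oxidative phosphorylation (NDUFC2 of 92), both with an adjusted p of 1. Of 41 small noncoding RNA genes, 1 was bound at an end, the vault RNA gene VTRNA1-2 (against 1.96% of other small RNA genes, exact test, adjusted p = 0.731). With a 2000 bp window or a peak in any library, immediate early genes (exact test, adjusted p = 0.00803 and 0.000821) and translation factors and tRNA synthetases (adjusted p = 0.0474 and 0.0126) passed the threshold, as did the unfolded protein response with any library (adjusted p = 0.00795). Over the 16 settings their odds ratios ran from 0 to 10.7, 4.69 and 6.15, and they did not pass in 14, 14 and 15 of them.

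**Figure D2:**
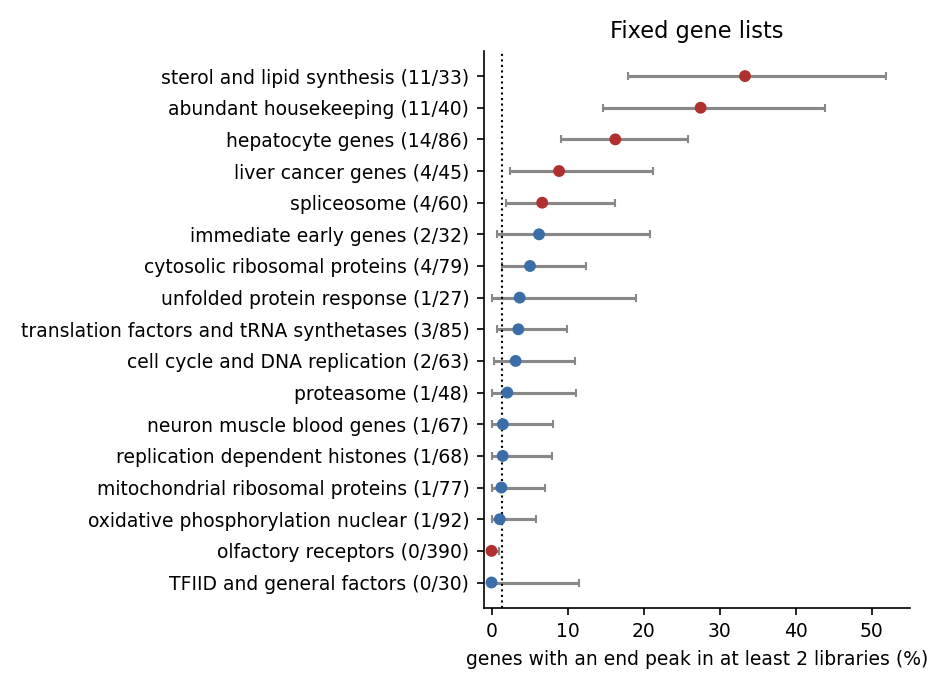
Share of the genes of each fixed list with a peak within 1000 bp of an end in at least 2 of 3 libraries, in percent, with exact binomial 95% intervals; the numbers beside each name are bound and tested genes. Red points mark lists past an adjusted p of 0.05 by Fisher's exact test and the dotted line the share over all protein-coding genes, 1.37%; the sterol and lipid synthesis list stands highest, at 33.3%.

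Among genes longer than 4000 bp, 228 had peaks of at least 2 libraries at 1 end only, and 3 had them at both ends. An end with a peak of 1 library was not counted, so a bound gene without 2 libraries at the same end is in neither count. The same rule was used for each end in what follows. For a subset of genes the start can be named, because the annotation holds a divergent transcript that carries the gene's symbol and lies beside it. Of 528 protein-coding genes longer than 4000 bp with such a partner within 2000 bp of an end, 9 were bound at the partner's end alone (ERRFI1, FN1, TWF2, SAP30, IRF2, TARS1, MTUS1, SQLE and NQO1). The opposite end alone was bound in 1 gene (GOT1), and both ends in IL6ST (exact two-sided binomial test of 9 against 1, p = 0.0215). GOT1 also had a peak of 1 library at the partner's end. This comparison was chosen after the data were seen.

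Away from all protein-coding gene ends, the highest-ranked regions shared by 3 libraries were in or near genes of varied function. The first lay inside C14orf93 (chromosome 14, 23006864 to 23007494, folds 22.4, 27.3 and 29.8). The next was inside TRIM71, a stem cell RNA-binding protein gene (chromosome 3, 32819353 to 32826696, folds 14.8, 16.1 and 14.2). It was followed by a region inside FDFT1, which encodes squalene synthase of the cholesterol pathway (chromosome 8, 11802459 to 11802798, folds 14.8, 13.3 and 12.2). Others lay inside DLGAP1 (chromosome 18, 3604775 to 3605210), ANKRD11 (chromosome 16, 89345649 to 89346008) and ZFHX3 (chromosome 16, 73055931 to 73056272). The remaining 4 were outside protein-coding genes, nearest to MAN1A1 (6002 bp away), SIAH2 (2846 bp), SLC6A11 (3574 bp) and NEDD4L (12261 bp). Mean rank percentiles of these 10 regions ran from 97.9 ± 1.63 at ZFHX3 to 99.9 ± 0.0628 at C14orf93 (SD, n = 3). Without transcripts it cannot be told whether the regions inside genes lay at internal transcription starts.

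A set of 32 regions exceeded 2000 bp in width, and all 32 held peaks of 3 libraries. Width is that of the region merged over libraries, so regions with more libraries tend to be wider by construction. Single peaks above 2000 bp numbered 20, 16 and 16 in replicates 1, 2 and 3. The widest regions lay over TRA2B (9849 bp), SNX5 and its small nucleolar RNA gene SNORD17 (7863 bp), UGDH (7356 bp) and TRIM71 (7344 bp), followed by the noncoding RNA gene ZFAS1 with its SNORD12 genes (6283 bp) and TGFBR2 (5928 bp). Wide regions also covered the noncoding RNA genes MALAT1 (5865 bp) and NEAT1 (2171 bp), and the genes MDM2 (5430 bp), NFE2L2 (3731 bp), GPC3 (3645 bp) and NPM1 (3383 bp). The summit fell inside an annotated gene of a numbered chromosome or X in 30 of the 32 wide regions (93.8%), against 883 of 1358 other reproducible regions (65.0%, two-sided Fisher's exact p = 0.000256). Mitochondrial and contig regions stayed in the totals but could not count as inside a gene. The other regions also included those with peaks of only 2 libraries, so the contrast is not of width alone. Peaks also gathered in dense clusters. Of 65 windows of 100 kb with 5 or more peaks of a library, 28 had 5 or more in each library, and the clusters held 24.0, 17.4 and 20.2% of the peaks of replicates 1, 2 and 3. The window at TRIM71 held 23, 21 and 19 peaks, that at EML4 18, 24 and 14, and that at TRIM24 14, 14 and 12.

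**Figure D3:**
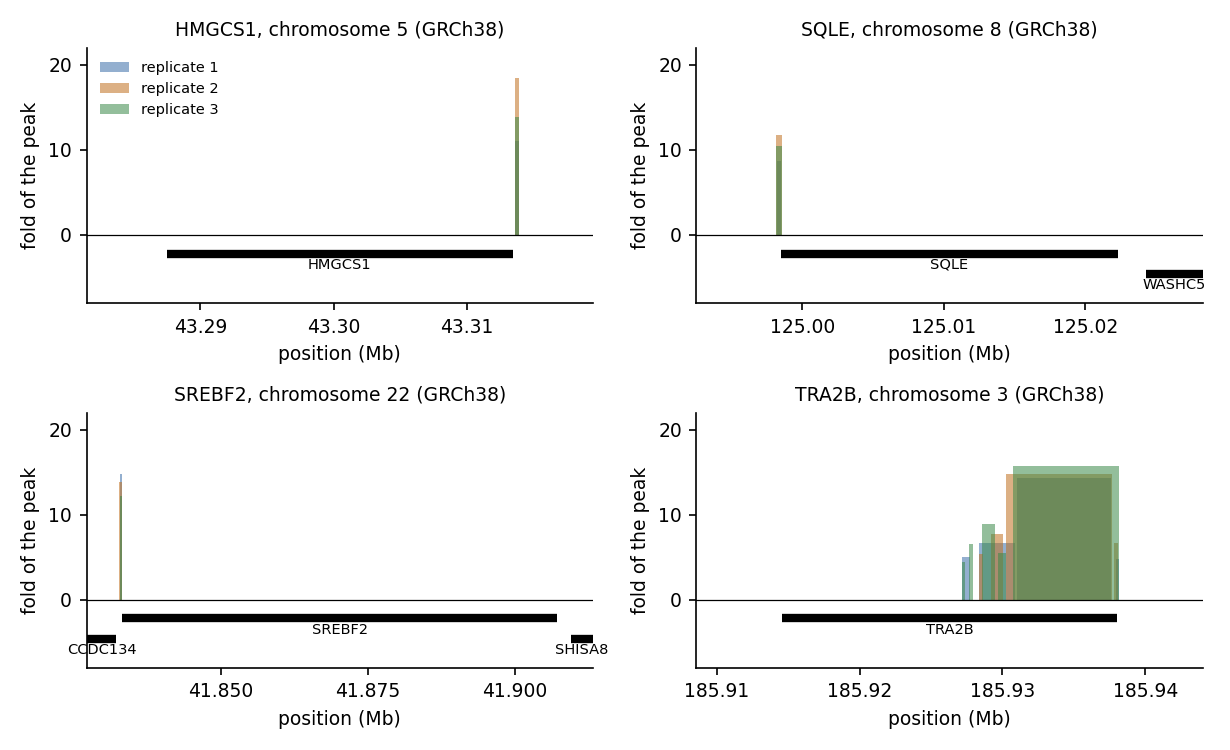
V5 peaks at HMGCS1, SQLE, SREBF2 and TRA2B, drawn over GRCh38 positions in Mb with the authors' fold of each peak as height, 1 colour per replicate, and protein-coding genes as black bars below; very narrow peaks are drawn at a minimum width. Peaks at HMGCS1, SQLE and SREBF2 are confined to 1 end of the gene and lie in regions of 326, 420 and 504 bp, while those at TRA2B spread over 9849 bp.

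The last comparison set the number of peaks on each chromosome against its share of protein-coding genes, since HepG2 is known to carry extra copies of some chromosomes. Chromosome 20 held 6.86% of reproducible regions against 2.69% of genes, a ratio of 2.55 (two-sided exact binomial test, adjusted p = 2.57e-14), and chromosome 2 held 10.8% against 6.28%, a ratio of 1.72 (adjusted p = 2.17e-09). The ratio was above 1 in each library for both, from 2.14 to 2.32 on chromosome 20 and from 1.64 to 1.75 on chromosome 2. Chromosome 17 was also above its share (1.27, exact binomial test, adjusted p = 0.0429). Fewer regions than the gene share lay, by the same exact test, on X (0.296, adjusted p = 2.17e-09), chromosome 19 (0.437, adjusted p = 2.01e-09), chromosome 13 (0.393, adjusted p = 0.00565), chromosome 11 (0.635, adjusted p = 0.000993) and chromosome 9 (0.625, adjusted p = 0.0129). Measured against chromosome length, chromosome 19 turned to an excess (ratio 1.64, exact binomial test, adjusted p = 0.0047) and chromosome 11 lost its deficit (0.901, adjusted p = 0.546). By length 11 chromosomes passed the threshold in place of 8: the ratio was 2.69 on chromosome 17 (exact binomial test, adjusted p = 2.05e-17) and 0.196 on chromosome 13 (adjusted p = 2.84e-10), and calls were gained on chromosomes 4 (0.417), 7 (0.642), 16 (1.71) and 22 (1.77). Without 1 replicate the calls on chromosomes 11 (0.711, adjusted p = 0.0806) and 17 (1.33, adjusted p = 0.0679) were lost in the absence of replicate 2, and those on chromosomes 9 (0.639, adjusted p = 0.0749), 13 (0.401, adjusted p = 0.0581) and 17 (1.314, adjusted p = 0.0746) in the absence of replicate 3, by the same exact test. The ratio of chromosome 19 was 0.28 without replicate 3 and stayed past the threshold. Without dense clusters the calls on chromosomes 9, 13 and 17 were lost (exact test, adjusted p = 0.0872, 0.0761 and 0.391), and at a fold of at least 5 those on chromosomes 11 and 17 (adjusted p = 0.135 and 0.473).

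**Figure D4:**
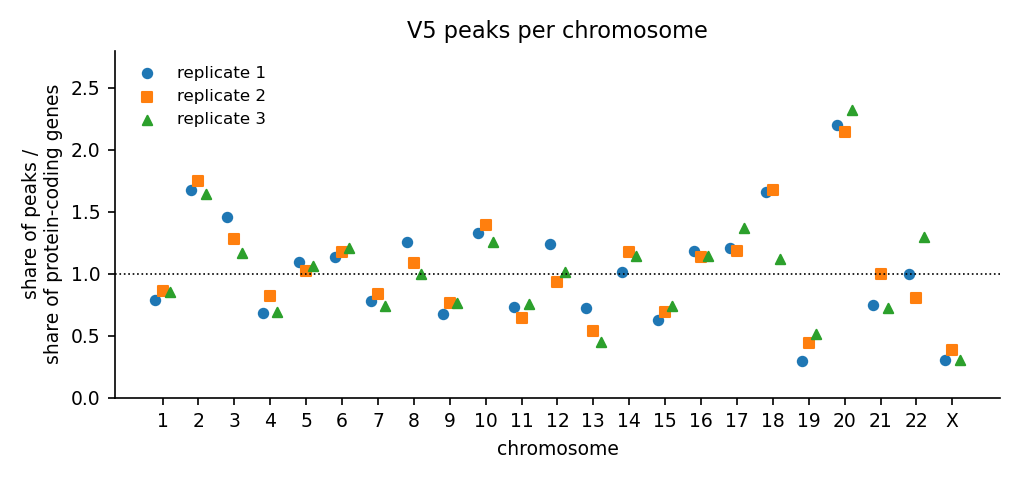
Share of each library's V5 peaks on a chromosome divided by that chromosome's share of protein-coding genes, with a point per replicate; the dotted line marks equal shares. All 3 replicates lie between 2.14 and 2.32 on chromosome 20 and between 0.303 and 0.384 on X.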

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

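All tests of explanations in this part were chosen after the results they address were seen. Outside the chromosomes used in the comparisons, peaks stood on contigs without annotated protein-coding genes. A contig assigned to chromosome 22 that carries ribosomal DNA repeats held 13, 12 and 14 peaks in replicates 1, 2 and 3, and an unassigned contig held 4, 4 and 5. These counts drew attention because they lie above 3, the limit that a count of 0 allows, in sequence left out of the gene-end share, class, distance, gene and chromosome comparisons, although these peaks count among the overlaps and shared regions. No control list was analysed here, so the same signal in the control libraries was not tested.

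The sterol and lipid synthesis list had the highest share of bound genes, and 3 technical explanations were tested. Extra chromosome copies in HepG2 were argued against, since the odds ratio was 53.7 (10 of 27 genes, interval 21.6 to 126.4) among genes outside chromosomes 2, 14, 16, 17 and 20, which HepG2 is known to carry in extra copies. Wide signal along transcribed genes was left undecided. The 11 regions of sterol genes had a median width of 265 bp, against 488 bp for 10 regions of housekeeping genes. The two-sided permutation p of 0.0461 was not adjusted over the 3 explanations. The widest regions were 504 bp in the sterol list and 1081 bp in the housekeeping list. Neither list therefore held a region of the width called wide here, so their contrast cannot test for wide signal. Abundant transcription stays open, since the list did not differ detectably from the abundant housekeeping list (33.3 against 27.5%, two-sided Fisher's exact p = 0.617), although it lay above the ribosomal protein list (5.06%, exact p = 0.000204). No biological explanation was tested, because the design has a single condition.

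The uneven number of peaks per gene between chromosomes may reflect extra chromosome copies. Chromosomes 2, 14, 16, 17 and 20 as a set held 1.63 to 1.73 times as many peaks per gene as the others in the 3 libraries (one-sided exact permutation over 33649 sets of 5 chromosomes, largest p = 0.00785). This set was taken from general knowledge of HepG2 after the chromosome ratios were seen. It includes chromosomes 2, 17 and 20, already above their gene share, so this p does not test copy number independently. Singly, by exact binomial tests, chromosomes 14 (1.22, adjusted p = 0.221) and 16 (1.12, adjusted p = 0.42) did not pass the threshold among reproducible regions. Dense clusters at a few loci were argued against as the whole cause, since without them the ratios were 1.56 to 1.62 (exact permutation, largest p = 0.00478). Copy number was not measured here, and no biological explanation was tested.

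The wide regions were weighed last, and abundant transcripts of the genes beneath stay open as a candidate explanation. Among reproducible regions with the summit in an annotated gene, 5 of 30 wide regions (16.7%) had it in a gene of the housekeeping, ribosomal protein, spliceosome, translation factor and noncoding RNA lists, against 35 of 883 others (3.96%, odds ratio 4.83, interval 1.36 to 13.9, two-sided Fisher's exact p = 0.00793). The noncoding list included the long noncoding genes MALAT1 and NEAT1. Without that list 3 of 30 wide regions (10%) against 34 of 883 others (3.85%) remained (exact p = 0.117). The direction stayed the same, but passing the threshold rests on that list. Expression was not measured here, and no biological explanation was tested.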

How the results depend on the processing

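The gene-body, local-shift, gene-length and shared-region alternatives were chosen after seeing the data, as were, for the gene lists, the choice of chromosomes and dense clusters and, for peaks per library, chromosomes and distance, leaving out a replicate. The others were planned. Of 523 values of the main comparisons under an alternative, 454 kept their direction and side of the threshold or stayed within their limits, 40 lost the threshold, 8 passed it, 20 moved and 1 reversed. The kept values were 74 of 95 for lists past the threshold, 182 of 190 for the other lists and 198 of 238 for the other results. Among the other results the gene-end share entered both as a share and as a ratio. The gene-end share of reproducible regions stayed above placement in 14 of 14 settings (ratio 3.26 to 5.75). Sterol, housekeeping and hepatocyte lists passed in 16 of 16 settings, with odds ratios of 20.3 to 55.5, 15.7 to 36.6 and 7.41 to 19.6. The single odds ratios and chromosome ratios that follow are values whose call was lost, apart from the reversed chromosome 19 and the olfactory list, described separately. With -log10 q of at least 5 the mean number of peaks was 958, shared regions 704, bound genes 131, the liver cancer odds ratio 7.14 and the chromosome 13 ratio 0.353. With fold of at least 5 they were 1080 peaks, 728 regions and 122 genes, the liver cancer odds ratio was 7.68, and the ratios of chromosomes 11 and 17 were 0.741 and 1.13. The strongest 1000 peaks of each list gave 691 shared regions. These filters remove peaks by construction. With -log10 q of at least 3, 3 lists passed, and liver cancer (4.76) and spliceosome (5.41) did not. Ranked by -log10 q, end peaks differed by -2.08 in replicate 1 and -4.26 in replicate 2. A 250 bp window gave 175 bound genes and a spliceosome odds ratio of 1.92, which was 2.65 with the summit inside the window and 2.86 over the gene body, where 751 genes were bound. With 3 of 3 libraries, 125 genes were bound, the liver cancer odds ratio was 7.49, 5 chromosomes passed, and the ratios of chromosomes 11, 13 and 17 were 0.722, 0.287 and 1.41. With any library, 802 genes were bound, 10 lists and 16 chromosomes passed, and chromosome 9 stood at 0.845. Without dense clusters, the odds ratios were 4.30 for liver cancer and 4.89 for spliceosome, and the ratios of chromosomes 9, 13 and 17 were 0.684, 0.489 and 1.13. By length, chromosome 11 stood at 0.901 and chromosome 19 reversed to 1.64, since chromosome 19 holds 7.26% of genes on 1.93% of the length. The olfactory odds ratio was 0 in every setting run, and its call was kept in 6 of 15. It was lost with -log10 q of at least 3 or 5, fold of at least 5, a 250 bp window, 3 of 3 libraries, no dense clusters, or any replicate left out. Leaving out each replicate gave 792 to 1002 shared regions, 157 to 204 bound genes, 3 to 5 lists and 6 to 10 chromosomes. The same settings gave 9.08 to 9.82% of summits inside other genes, odds ratios of 5.71 to 9.17 for liver cancer and 6.50 to 7.04 for spliceosome. Ratios were then 0.643 to 0.711 on chromosome 11, 0.304 to 0.401 on 13, 1.314 to 1.35 on 17 and 0.509 to 0.639 on 9. Where no construction is named, the cause was not tested. Adjusted p-values over the settings reached 0.19 for liver cancer, 0.579 for spliceosome and 0.542 for olfactory receptors. Of 65 named entries, 55 were bound in at least 2 libraries and 20 kept that in all 7 settings tried for them. Not run, for lack of strand, transcripts or sequence, were 1 start per gene, the CpG model, the CpG-rich background, and core promoter sequence with its alternatives, GC matching included. No paired analysis was possible because the labels pair no samples and the controls were not analysed here. Depth is unknown, so what it limits could not be given.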

Other observations

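The gene types and the noncoding genes in this part were examined after the data were seen, and the tests on NRF2 and p53 targets were written before their members' values were seen. Small nucleolar RNA genes, which guide modification of ribosomal RNA, had an end peak in at least 2 libraries in 30 of 1196 cases (2.51%), against 1.307% of nuclear protein-coding genes (two-sided Fisher's exact test, adjusted p = 0.00557). Ribosomal RNA genes did so in 4 of 49 cases (8.16%, exact test, adjusted p = 0.00797). Transfer RNA genes, which RNA polymerase III transcribes, were bound in 0 of 443 cases (exact upper limit 0.829%, adjusted p = 0.0119). Long noncoding RNA genes (0.798%, exact test, adjusted p = 6.92e-06) and microRNA genes (0.733%, adjusted p = 0.0371) lay below protein-coding genes, and 0 of 154 small nuclear RNA genes were bound (adjusted p = 0.273). Small genes inside a wide region over a host gene count as bound with it. The windows at both ends of a short gene largely coincide, so small RNA genes were scored over less sequence than long protein-coding genes. This was not corrected for, so the low shares of microRNA, transfer RNA and small nuclear RNA genes are not directly comparable with that of protein-coding genes.

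The long noncoding RNA genes MALAT1 and NEAT1, whose transcripts stay in the nucleus, had peaks over their spans in 3 libraries, with highest folds of 9.77, 8.72 and 10.1 at MALAT1 and 5.79, 5.52 and 4.87 at NEAT1 in replicates 1, 2 and 3. The vault RNA gene VTRNA1-2 had a peak in each library, with folds of 5.30, 6.10 and 5.89. On chromosome 16, a stretch without annotated genes from 36102206 to 46469336 held 6 peaks in each library, between 46386351 and 46398824. The mitochondrial genome held 18, 13 and 16 peaks, of median rank percentile by fold 1.69, 1.17 and 1.35. Their median -log10 q was high, at 18.5, 29.7 and 16.3 in replicates 1, 2 and 3. Over all peaks of these lists the median -log10 q was 4.72, 4.86 and 4.88.

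NFE2L2, which encodes the oxidative stress regulator NRF2, was bound together with targets such as NQO1, UGDH and FTL, so NRF2 targets as a group may carry end peaks. Among 24 targets other than those noticed first, 2 were bound, PRDX1 and GCLM (8.33%, odds ratio 6.58, interval 0.746 to 27.0). The two-sided Fisher's exact p of 0.0424 was below the threshold named beforehand, and adjusted over the 2 hypotheses tested it was 0.0848, which leaves the hypothesis open.

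MDM2, a target of p53, was among the strongest end genes, so targets of p53 as a group might be bound. Of 30 other targets 0 were bound (odds ratio 0, interval 0 to 9.46, two-sided Fisher's exact p and adjusted p of 1). The absence of a bound gene was the outcome named beforehand as against the hypothesis, and it was met. An interval that wide still leaves the hypothesis open.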
